A study of Mus musculus with 6 samples.

How the data were processed

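RNA of MC3T3-E1 cells, a mouse pre-osteoblast line from calvaria, was measured on 6 NimbleGen expression arrays with 1 dye, 3 for undifferentiated cells and 3 for cells after 15 days of osteogenic medium. Groups and replicate numbers came from the sample labels, and the design text gives the samples as biological triplicates. The labels' protocols also mention treatment with the hormonal form of vitamin D, and such samples are not analysed here.

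Each array's file held 1 intensity per transcript row on a linear scale, as deposited by the authors and made with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a row. The RMA version and whether all 6 arrays went through 1 run are not given in the sources used here. Of 42586 rows, 42566 were summarised from 9 probes and 20 from fewer. A control row summarised 6131 random-sequence probes and was used to judge background, because the files gave no detection calls. The deposited series table held the same intensity values. Its columns for differentiated replicates 1 and 2 carried the values of each other's files (42586 equal rows, exact match), which changes replicate numbers and no group. Replicate numbers here follow the files per array.

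The accessions in the files were RefSeq mRNA (18952 rows), predicted RefSeq (6487) and GenBank (17147) entries. A RefSeq gene table of assembly GRCm38.p6, used for names and neighbours alone, named 17846 rows as 17295 genes. The other 24740 rows stayed unnamed and out of the main counts. For 467 genes with more than 1 row, the row with the highest mean over the arrays stood for the gene. In 10 of them rows disagreed in sign with p under 0.05 in each direction, and 0 of these were in a gene list.

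Intensities were converted to log2 with no filter on low values. Before the data were examined, the plan named the tests, the alternatives, 28 gene lists and the rule for named genes. It foresaw arrays with equal distributions, overall or within groups. The sorted values turned out close and not equal in either sense, so the values were used as deposited, with quantile normalization of the arrays as an alternative. Differentiated and undifferentiated cells were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 6.01 prior degrees of freedom) and Benjamini-Hochberg adjustment, with 0.05 as the threshold. Errors are standard errors from that fit. Log2 changes are differentiated minus undifferentiated. The fold of Cd200 was bounded with the random control in place of its undifferentiated values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and plots.

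The lists held 635 entries, of which 612 were measured (586 distinct genes). They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28 lists, with camera at an estimated correlation and with fry beside it. Camera called 10 lists, and 0 of the 10 kept the call with an estimated correlation. The estimated correlations of those 10 ran from 0.00403 to 0.61, so the lost calls do not all rest on correlated genes. Fry asks whether a list's genes move on balance one way and compares them with no other genes.

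The rule for named genes took Runx2, the 10 largest rises and 10 largest falls among changed genes without overlap between groups, up to 2 members per direction from each list, and any member of the lists of osteoblast transcription factors and of maturation and mineral genes. Further list members in the report, such as Col1a1, Sost, Dkk2, Wnt5a, Axin2, Fgf1, Igf1, Fgfr2, Ctsk, Smtn, Msmo1, Fdps, Sqle, Birc5, Ldha, Cxcl12, Tnfsf11, Cyp24a1, Sox9, Pparg and Gapdh, were chosen after their values were seen. Some genes that the rule names are not reported here.

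Alternatives were quantile normalization, median centring, cyclic loess, the series table, filters at the median and at the 25th percentile of mean level, the mean over rows of a gene, every row on its own, eBayes with trend and robust settings, the replicate number as a block, and leaving out each array. The steps were tested on simulated arrays with the real means and spreads. With 17295 genes, 40% of 100 genes changed 1.5-fold, 84% of 50 changed 2-fold and 100% of 50 changed 4-fold were recovered, with 8 false among 140 calls. The changed genes were far fewer than the 2330 called in the data. Benjamini-Hochberg adjustment depends on that share, so these recovery rates need not hold for the data. Arrays simulated without any change gave 0 genes and 0 lists. Genes were drawn independently of each other there, while mitotic genes had an estimated correlation of 0.61 in the data. The 0 lists therefore do not show that camera avoids false calls for lists of correlated genes.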

Results

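Transcript levels were measured on 1-colour expression arrays in MC3T3-E1 cells, a mouse pre-osteoblast line from calvaria that makes mineralised matrix when given ascorbic acid and a phosphate donor. 3 arrays carried RNA of undifferentiated cells. 3 others carried RNA of cells kept for 15 days with 10 mM glycerol-2-phosphate and 50 ug/mL ascorbic acid. All 6 cultures had ethanol vehicle for 24 hours, and the study design describes the replicates as biological. Each array gave 42586 transcript rows, with median intensities of 806 to 845 and 101 to 114 for the random-sequence control probes. Between 5.75% and 6.77% of rows lay below that control on an array. Values across rows correlated at 0.986 to 0.996 within groups and at 0.968 to 0.980 between them. The number of arrays, 3 per group, limits the precision.

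The comparison addressed how the transcriptome of pre-osteoblasts differs after osteogenic culture, which the series sets beside genome occupancy by RUNX2 (not analysed here). After differentiation, 11 of 25 genes of osteoblast maturation and mineral deposition rose, among them the phosphatase Alpl and the matrix phosphoprotein Dmp1, and 10 of 24 genes of IGF and FGF signalling rose, among them Igf2. Of the genes for cholesterol synthesis 19 of 25 fell, and of those for mitosis 19 of 27. These 4 lists passed with camera at its preset correlation and with fry, and missed the threshold with an estimated correlation (adjusted p = 0.134, 0.383, 0.383 and 0.47). Of 17295 named genes, 1198 rose and 1132 fell with limma, 2330 in all, and 305 rose and 154 fell at least 2-fold. The balance of all rises and falls depended on the setting, as 1017 rose and 1173 fell with each array centred on its median. At least 4-fold changes comprised 72 rises and 15 falls. At an unadjusted p under 0.05 there were 4577 genes. In 5445 genes (31.5%, against 10% by chance) the arrays of the groups did not overlap. The 2330 changed genes became 3549 without undifferentiated replicate 3, 1436 without differentiated replicate 1 and 1092 without differentiated replicate 2. The image names gave each group 1 date with 0 dates shared, so array batch and group cannot be told apart. The labels give no group kept for 15 days without the additives. Effects of time in culture and of the additives therefore cannot be told apart either.

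The 10 largest rises spanned 14.5- to 102-fold. F13a1, the transglutaminase chain of coagulation factor XIII, rose from a mean intensity of 218 to 22328 (log2 change 6.68, SE 0.19, n = 3 per group). Igf2 rose from 762 to 29233 (5.26, SE 0.18) and the collagenase Mmp13 from 542 to 18013 (33.2-fold, log2 SE 0.13). Cd200, a membrane glycoprotein that restrains myeloid cells, reached 8348. All 3 undifferentiated arrays lay below the random control for it, so the rise was at least 76.6-fold against that control. The others were Itgbl1 (5.04), the chemokine-scavenging receptor Ackr4 (3.96), Tnfrsf19 (3.95), the kinase scaffold Akap12 (3.94), the laminin receptor chain Itga6 (3.92) and Col15a1 (3.86).

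The 10 largest falls spanned 4.54- to 24.0-fold. The chemokine Ppbp fell by 4.58 (SE 0.16, n = 3 per group) and Bmper, a secreted BMP-binding protein, fell by 4.09 (SE 0.14) on the log2 scale. The interleukin 18 receptor chain Il18rap fell by 3.54 and the kinase-like Styk1 fell by 2.67. Ndufa1, a subunit of respiratory complex I, fell by 2.63 (SE 0.26), and the gene next to it, Rnf113a1, fell by 2.20 (SE 0.14). The others were the nicotinic receptor subunit Chrna5 (-2.51), the imprinted gene Peg10 (-2.41), the fatty acid elongase Elovl7 (-2.36) and Anxa8 (-2.18).

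**Figure D1:**
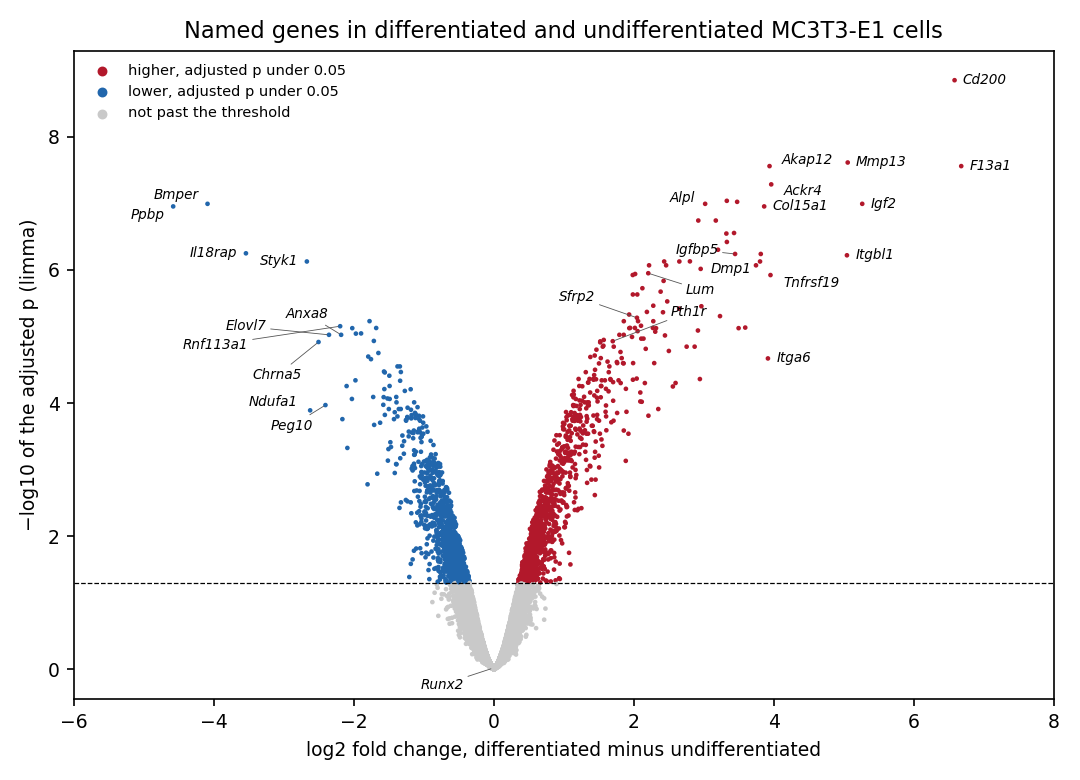
Each point is 1 of 17295 named genes; the horizontal axis is the log2 fold change, differentiated minus undifferentiated (n = 3 arrays each), the vertical axis is -log10 of the adjusted p from limma, and the dashed line marks 0.05. The points past 4-fold lie mostly on the right, 72 higher against 15 lower, with Cd200 and F13a1 farthest out and Runx2 at the foot.

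Runx2, the transcription factor that commits cells to the osteoblast lineage and the subject of the series, did not pass the test. Its single row had mean intensities of 5688 in undifferentiated and 5631 in differentiated cells. The log2 difference was -0.01 (SE 0.12, 95% interval -0.28 to 0.25, n = 3 per group), which corresponds to a change between -17.7% and 19.1%. The adjusted p was 0.959 with limma, and a two-sided exact permutation test over the 6 arrays gave 1, where 0.1 is the smallest value possible. The sign turned with quantile normalization (0.02), with cyclic loess (0.03), without undifferentiated replicate 3 (0.04) and without differentiated replicate 1 (0.06), in each case short of the threshold.

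Of 25 measured genes of osteoblast maturation and mineral deposition, 11 rose and 1 fell (14 and 1 when adjusted over the list alone). Alpl, which frees phosphate for mineral, rose 8.10-fold from 747 to 6054 (log2 change 3.02, SE 0.10, n = 3 per group). Dmp1 rose 7.75-fold from 331 to 2562 (2.95, SE 0.14). The parathyroid hormone receptor Pth1r (1.70), the fibrillar collagen Col24a1 (1.32), the matrix vesicle phosphatase Phospho1 (1.32), the secretory kinase Fam20c (1.23) and osteomodulin, Omd (1.16), followed. The osteocalcin genes Bglap (0.82) and Bglap2 (0.78) are near-identical copies, so neither value is certain to be its own. Matrix Gla protein, Mgp, an inhibitor of calcification, fell from 51297 to 24067 (-1.09, SE 0.11). The late markers Spp1 (-0.10) and Ibsp (0.43, adjusted p = 0.12) did not pass, and Phex lay below the random control on all 6 arrays. Ibsp was weak, at mean intensities of 189 in undifferentiated and 255 in differentiated cells, under the array medians, so it tests a rise less well. Ibsp passed without undifferentiated replicate 3 (adjusted p = 0.0235). The list had adjusted p = 9.16e-07 with camera and adjusted p = 0.134 with an estimated correlation.

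**Figure D2:**
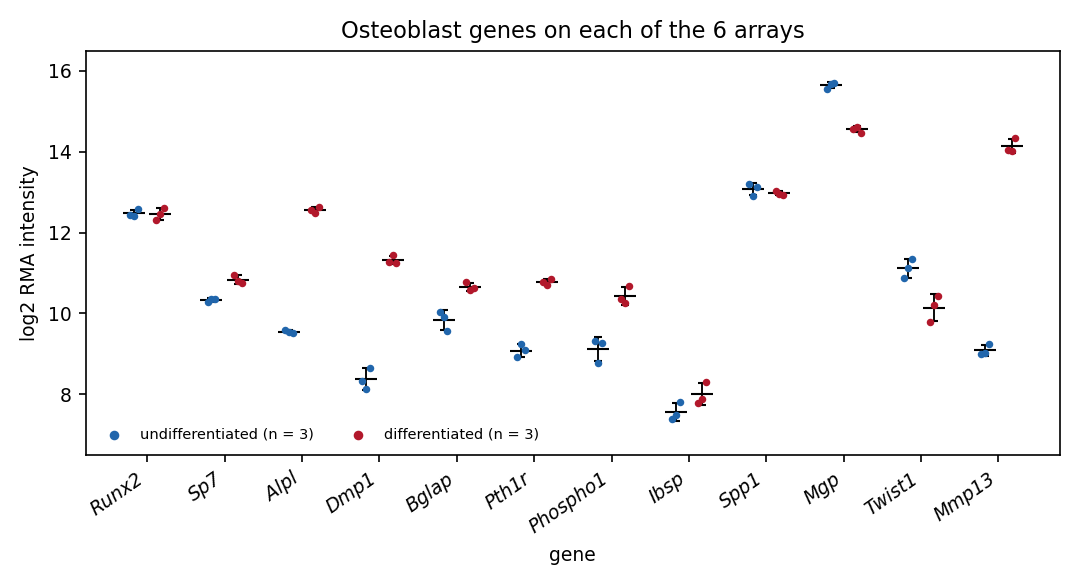
Points are log2 RMA intensities (vertical axis) of 12 osteoblast genes (horizontal axis) on each array, blue for undifferentiated and red for differentiated cells; black dashes and bars give the mean and SD of 3 arrays. Alpl, Dmp1 and Mmp13 separate the groups by 2.95 or more, while Runx2 (-0.01) and Spp1 (-0.10) lie at like levels in both.

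Most structural matrix genes did not pass, with 5 of 28 higher and 1 lower (6 and 3 adjusted over the list alone). Lumican, Lum (2.21, SE 0.11), and tenascin C, Tnc (2.04, SE 0.17), rose. The prolyl hydroxylase P4ha2 fell by 0.70, a call that ended without differentiated replicate 2 (adjusted p = 0.0579). The type I collagen genes Col1a1 (0.10) and Col1a2 (0.07) did not pass. Of 13 osteocyte genes 3 rose and 1 fell, the same counts when adjusted over the list alone: Dmp1, Fam20c and the ectonucleotidase Nt5e (2.43, SE 0.11) rose, and the hyaluronan receptor Cd44 fell by 0.63 (adjusted p = 0.0518 without differentiated replicate 2). Sclerostin, Sost, stood at -0.06. Adjusted p from camera was 0.0755 for the matrix list and 0.197 for the osteocyte list, whose median (-0.05) and mean (0.45) differ in sign. The matrix list passed with every row tested (0.0488), with eBayes trend and robust settings (0.0206), without undifferentiated replicate 3 (0.0215) and with fry (0.036).

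Osteoblast transcription factors moved both ways, with 8 of 35 higher and 6 lower (10 and 7 adjusted over the list alone). The Wnt effectors Lef1 (0.95) and Tcf7 (0.53), the Iroquois factor Irx3 (1.14, SE 0.11), Zfp521 (0.78), Hoxa10 (0.71), Cebpb (0.59), Sox4 (0.39) and Sp7 (0.50) rose. Sp7 encodes osterix, which acts after RUNX2 in the lineage. The AP-1 members Fosl1 (-1.34, SE 0.11) and Junb (-0.69), the inhibitor Id4 (-1.13), Twist1 (-0.97), Tead1 (-0.73) and Dlx5 (-0.71) fell. Atf4 (-0.33) and the RUNX2 partner Cbfb (-0.46, adjusted p = 0.0577) did not pass. The list as a whole had adjusted p = 0.794 with camera. The calls were 9 in place of 14 without differentiated replicate 2: the adjusted p was then 0.0699 for Sp7, 0.0701 for Tcf7, 0.0983 for Cebpb, 0.181 for Sox4 and 0.0623 for Junb. Of the 6 leave-outs, Sox4 kept its call only in that without undifferentiated replicate 3. Tcf7 (0.0574) and Cebpb (0.0696) also missed it without undifferentiated replicate 1, and Cebpb without differentiated replicate 3 (0.0643). Sp7 also missed the threshold without undifferentiated replicate 1 (0.0539) and without differentiated replicate 1 (0.0604), and Cbfb passed without undifferentiated replicate 2 (0.0437) or differentiated replicate 3 (0.0478). Cbfb also passed with quantile normalization (0.0256), cyclic loess (0.0403) and the filters at the median (0.0341) and the 25th percentile (0.0482).

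The IGF and FGF signalling list, which holds ligands, receptors, binding proteins and feedback inhibitors, had 10 of 24 members higher, 1 lower and 13 that did not pass (11 higher and 1 lower adjusted over the list alone). Besides Igf2, the binding protein Igfbp5 rose by 3.45 (SE 0.15, n = 3 per group), Fgf1 by 2.46, Igfbp2 by 1.67 and Igf1 by 1.52. The receptors Fgfr2 (1.23) and Fgfr3 (1.17) rose, while the receptor Igf1r fell by 1.34 (SE 0.11). For the list, camera gave adjusted p = 9.23e-06, and adjusted p = 0.383 with an estimated correlation.

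Wnt pathway genes changed in both directions, 8 of 34 higher and 5 lower (10 and 6 adjusted over the list alone). The Wnt amplifier Rspo2 (2.56, SE 0.22) and the Wnt antagonists Sfrp2 (2.04, SE 0.12) and Dkk2 (1.46) rose. The ligands Wnt10b (-1.49, SE 0.14) and Wnt5a (-1.06) and the matricellular Ccn5 (-1.65) fell. Axin2, a feedback target of the pathway, stood at 0.18 (adjusted p = 0.42). In the BMP and TGF-beta list 5 of 34 rose and 2 fell, the same counts adjusted over the list alone. The ligands Bmp4 (1.08, SE 0.12) and Tgfb2 (1.02, SE 0.14) rose and the activin subunit Inhba fell by 0.79. Neither list passed with camera (adjusted p = 0.439 for Wnt and 0.133 for BMP and TGF-beta genes).

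Among matrix proteases and their inhibitors 8 of 25 rose and 2 fell, also when adjusted over the list alone. Mmp13 led, with the inhibitor Timp4 (1.03, SE 0.13) and the cathepsins Ctsb (1.00) and Ctsk (0.99). Urokinase, Plau, fell by 1.50 (SE 0.15). The protease list had adjusted p = 0.00603 with camera, and adjusted p = 0.512 with an estimated correlation. Contractile genes of the smooth muscle type rose in 7 of 15 members and fell in 0 (7 and 2 adjusted over the list alone), among them Mylk (1.48, SE 0.14), Acta2 (1.11, SE 0.14) and Smtn (1.02). Their adjusted p was 0.0118 with camera and 0.383 with an estimated correlation. Adhesion genes moved both ways, 4 of 23 higher and 6 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.817). Itga6 and Itga8 (1.47) rose, and the gap junction protein connexin, Gja1 (-1.51, SE 0.18), and Vcam1 (-1.07) fell. Without differentiated replicate 2, 5 adhesion genes passed in place of 10.

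Cholesterol synthesis genes fell together: 19 of 25 were lower and 0 higher (22 and 0 adjusted over the list alone), with a median log2 change of -0.75. Lanosterol synthase, Lss, fell by 1.22 (SE 0.14, n = 3 per group), as did Msmo1 (-1.14, SE 0.14), the farnesyl diphosphate synthase Fdps (-1.05, SE 0.12) and squalene epoxidase, Sqle (-0.85, SE 0.16). The fall had adjusted p = 2.24e-14 with camera, and adjusted p = 0.383 with an estimated correlation.

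Mitotic genes fell in 19 of 27 members and rose in 0 (23 and 0 adjusted over the list alone), with a median of -0.70. The ubiquitin-conjugating enzyme Ube2c fell by 1.14 (SE 0.15), as did the cyclin Ccnb1 (-1.16, SE 0.28) and survivin, Birc5 (-0.93). The differentiated arrays were uneven in this list, at mean deviations of -0.55, -0.45 and -0.01 for replicates 1, 2 and 3, against 0.30, 0.27 and 0.44 in undifferentiated cells. The calls numbered 12 without undifferentiated replicate 1, 9 without differentiated replicate 1 and 6 without differentiated replicate 2. Ccnb1 was among those lost (adjusted p = 0.0529, 0.0774 and 0.0864 without undifferentiated replicate 2, differentiated replicate 1 and differentiated replicate 2). Adjusted p for mitotic genes was 1.14e-13 with camera, and adjusted p = 0.47 with an estimated correlation. DNA replication genes fell in 5 of 31 members and rose in 0, the same counts adjusted over the list alone, among them Cdt1 (-0.68, SE 0.17), which licenses replication origins. These had adjusted p = 0.00103 with camera, and adjusted p = 0.703 with an estimated correlation. The 5 became 2 without undifferentiated replicate 1 or 2, and 0 without differentiated replicate 1 or 2. Cdt1 also missed the threshold without undifferentiated replicate 2 (adjusted p = 0.0699). The groups overlapped in the mean deviation of the replication list. It was -0.263, -0.130 and 0.052 in differentiated replicates 1, 2 and 3, against 0.039, 0.029 and 0.273 in undifferentiated cells.

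**Figure D3:**
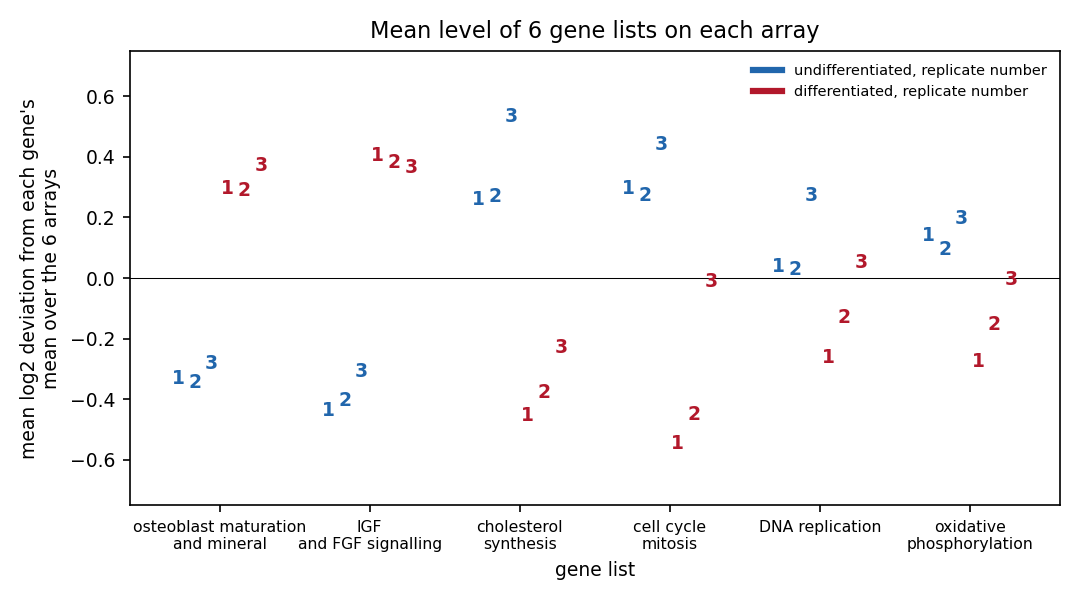
Numbers mark the replicates of undifferentiated (blue) and differentiated (red) cells; the vertical axis is the mean log2 deviation of a list's genes from their means over the 6 arrays, for 6 gene lists on the horizontal axis. Mitotic genes lie at -0.55, -0.45 and -0.01 in differentiated replicates 1, 2 and 3, while the mineral list lies between 0.29 and 0.37 in all 3.

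Genes of oxidative phosphorylation fell in 7 of 30 members and rose in 0 (10 and 0 adjusted over the list alone), with Ndufa1 and the ATP synthase subunit Atp5j (-0.78, SE 0.15) lowest and a list median of -0.28. As a group they had adjusted p = 0.00147 with camera, and adjusted p = 0.518 with an estimated correlation. The calls numbered 4 without undifferentiated replicate 2, differentiated replicate 1 or differentiated replicate 2. In the hypoxia and glycolysis list, the carbonic anhydrase Car9 (1.17, SE 0.16) and the mitophagy receptor Bnip3 (0.88, SE 0.12) rose, 2 of 24, also adjusted over the list alone, and 0 fell. Glycolytic enzymes such as Ldha (0.10) and Pkm (-0.18) did not pass. Camera gave adjusted p = 0.0321, and adjusted p = 0.471 with an estimated correlation. The list missed the threshold without undifferentiated replicate 1 (0.121), undifferentiated replicate 2 (0.061) or differentiated replicate 1 (0.0568), and 5 members passed without undifferentiated replicate 3.

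Interferon-response genes fell in 7 of 27 members and rose in 0 (9 and 1 adjusted over the list alone), with Ifit1 (-1.10, SE 0.19) and Ifi44 (-0.95, SE 0.20) lowest. The group had adjusted p = 0.00289 with camera, and adjusted p = 0.471 with an estimated correlation; 4 members passed without differentiated replicate 2. Inflammation genes split into 6 higher and 5 lower of 25 (7 and 7 adjusted over the list alone). Complement C3 (2.12, SE 0.11) and Icam1 (1.11) rose, and the interleukin 33 receptor Il1rl1 (-2.11, SE 0.18) and Vcam1 (-1.07, SE 0.11) fell. The median (0.07) and mean (-0.05) of the list differ in sign, camera gave adjusted p = 0.835, and 7 passed in place of 11 without differentiated replicate 2. Of 11 genes that regulate osteoclasts 0 rose and 3 fell (0 and 4 adjusted over the list alone), Il1rl1, the cyclooxygenase Ptgs2 (-1.35) and Cxcl12 (-0.83). The ligand Tnfsf11 (0.15) and its decoy receptor Tnfrsf11b (0.10) did not pass, and the list's median (0.05) and mean (-0.35) differ in sign (camera adjusted p = 0.17).

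Vitamin D signalling genes numbered 1 higher and 1 lower of 16, also adjusted over the list alone (camera adjusted p = 0.651). Mmp13 rose and the receptor partner Rxra fell by 0.96, while the receptor Vdr (0.09) and its target Cyp24a1 (0.03) did not pass. In the list of endoplasmic reticulum stress and amino acid genes, 1 of 25 rose and 2 fell (2 and 2 adjusted over the list alone), with Atf3 at 0.78 (SE 0.13) and Sesn2 at -0.67. Camera gave adjusted p = 0.395, and 0.0476 without differentiated replicate 3. The 3 calls became 5 without undifferentiated replicate 3 and 1 without differentiated replicate 1 or 2, where Sesn2 missed (0.0629 and 0.0813), as it did without undifferentiated replicate 2 (0.0544).

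Markers of other cell types moved in some members of the chondrocyte, adipocyte, skeletal muscle and endothelial lists. In these lists of 12 to 18 genes the changed shares lay above the 13.5% of all genes. Chondrocyte genes rose in 4 of 18 and fell in 0, also adjusted over the list alone, with Cnmd (3.80, SE 0.18) and Col11a1 (2.94, SE 0.25) highest, while Col2a1 (0.12), Acan (0.13) and Sox9 (0.03) did not pass. Camera gave adjusted p = 0.0658. The list passed without undifferentiated replicate 2 (0.0409) or differentiated replicate 3 (0.0274), with the filter at the median level (0.0103), with every row tested (0.046), with eBayes trend and robust settings (0.0295) and with fry (0.00573). Adipocyte genes numbered 3 higher and 1 lower of 17 (3 and 2 adjusted over the list alone), with Cebpa at 0.94 (SE 0.11) and Pparg at 0.37 (adjusted p = 0.13). Skeletal muscle genes numbered 2 higher and 1 lower of 16, led by Tnnt1 (2.05, SE 0.14), and endothelial genes 2 higher and 0 lower of 12, led by Tek (1.51, SE 0.17), with the same counts adjusted over each list alone. Camera gave adjusted p = 0.556, 0.302 and 0.174 for these 3 lists. The calls fell to 1 in the adipocyte list without undifferentiated replicate 1 or differentiated replicate 2, and to 1 in the muscle and endothelial lists without undifferentiated replicate 2, differentiated replicate 1 or differentiated replicate 2.

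No call was made in the tenocyte list (0 of 9, with Fmod at 0.27), the macrophage and osteoclast list (0 of 15, with Fcer1g at 0.35) or the neural list (0 of 12, with Gap43 at 0.19), with limma over all genes or adjusted over each list alone. At an unadjusted p under 0.05 there were 3, 2 and 0 genes. Adjusted p was 0.56, 0.6 and 0.794 with camera, and 0.0395 (upward), 0.302 and 0.832 with fry. Housekeeping genes stayed near 0 with a median of -0.10, and camera gave adjusted p = 0.395. Gusb rose by 0.53 and Rplp0 (-0.94, SE 0.22) and Tfrc (-0.77, SE 0.21) fell, 3 of 16, also adjusted over the list alone, but 0 passed without undifferentiated replicate 1 or differentiated replicate 2. Tfrc also missed the threshold without differentiated replicate 1 (0.123) and with cyclic loess (0.0663), and Gusb without differentiated replicate 3 (0.0599). Actb stood at -0.23 and Gapdh at -0.11.

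**Figure D4:**
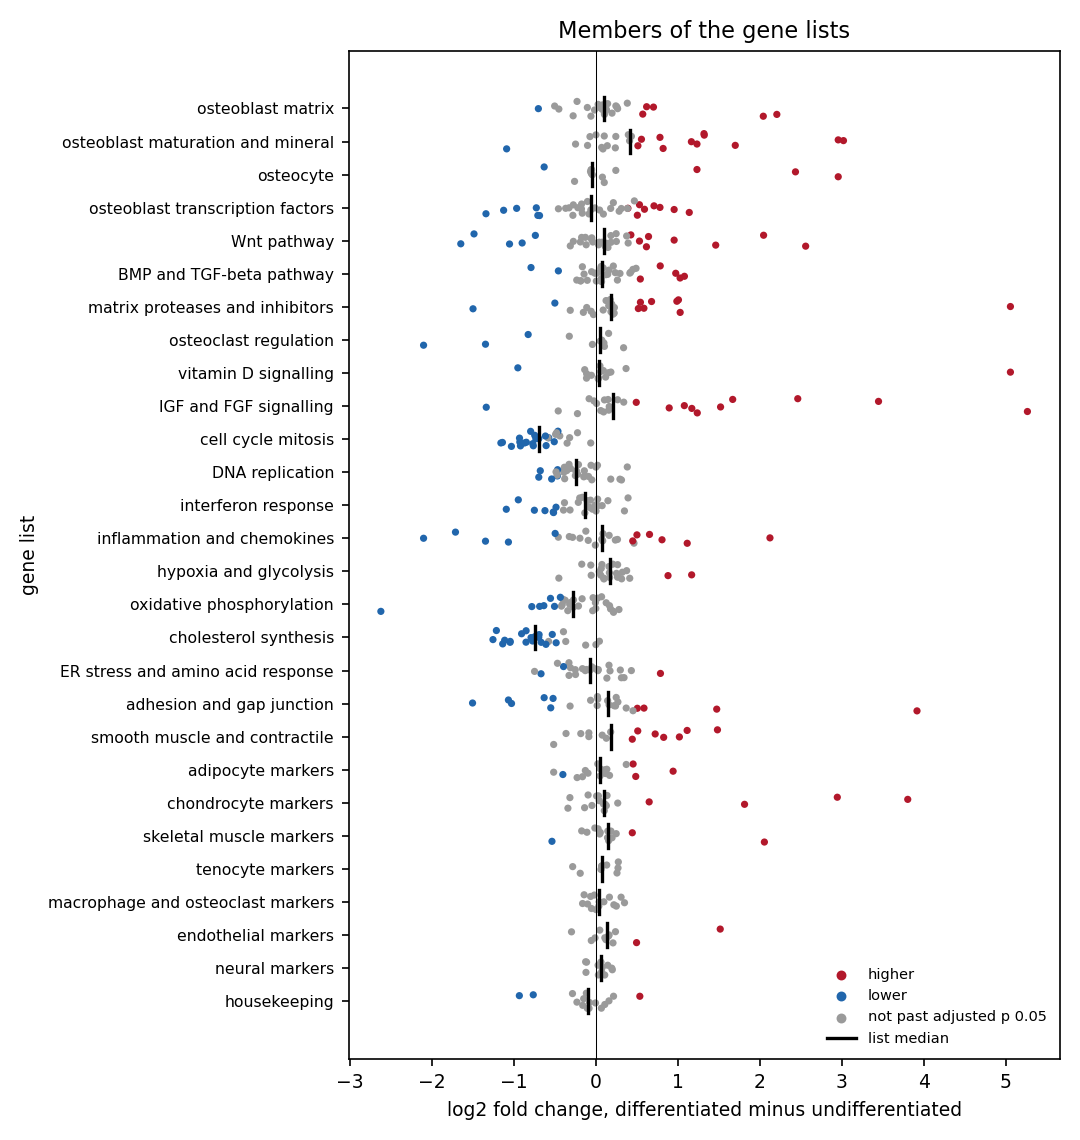
Each point is a gene of 1 of the 28 lists (vertical axis) at its log2 fold change, differentiated minus undifferentiated (horizontal axis, n = 3 arrays each); red and blue mark adjusted p under 0.05, and black bars the list medians. The cholesterol and mitosis lists lie to the left as a whole, with medians of -0.75 and -0.70, and the mineral list to the right, at 0.41.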

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

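The covariate for the first component of the spread within groups and the list counts without each array were chosen after the data were seen; the other settings were planned. The direction and threshold side stayed the same in 457 list tests and 2040 named-gene tests over the alternatives; 18 list tests and 74 named-gene tests fell below the threshold, and 16 and 27 rose past it. The cause of these shifts was not tested. The series table held the same values in the same groups, so its tests among the unchanged ones were fixed in advance. Undifferentiated replicate 3 had the largest weight (0.707) on the first component of the spread within groups. It was the only array whose omission raised the count of changed genes. The count of 2330 changed genes ran from 1092 to 3549 without 1 array and was 5642 with that component as a covariate. The component was taken from these same arrays and holds 67.8% of the variance within groups. Removing it raises the count by construction. Testing every row gave 6037 changed rows, 1042 of them at least 2-fold, as more rows enter. Quantile normalization gave 2953, median centring 2190 and cyclic loess 2785 genes. Falls outnumbered rises with median centring (1173 against 1017), with every row tested (3243 against 2794), without genes below the median mean (1110 against 988), with trend and robust moderation (1267 against 1236), with the replicate block (1998 against 1976) and without undifferentiated replicate 1 (779 against 777), undifferentiated replicate 2 (863 against 815) or differentiated replicate 3 (1017 against 834). With the replicate number as a block there were 3974 changed genes; this uses the numbers of the files per array, and which numbering of differentiated replicates 1 and 2 is right is not known. Same-numbered arrays correlated in their deviations at 0.414, -0.108 and 0.567, or at -0.012, 0.518 and 0.567 with the series table's numbers. Neither has every pair over 0.1, so the numbers were not taken to pair the samples, and not every array matched best with its own number. With the block, 7 named genes passed that had not: Ank (0.0153), Cbfb (0.00723), Dlx3 (0.015), Fosb (0.0491), Ggcx (0.0146), Ibsp (0.00834) and Runx1 (0.0233).

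Runx2 turned sign with quantile normalization (0.01894) and cyclic loess (0.03215), and ranged from -0.09345 to 0.0636 without 1 array. So did Vkorc1 (0.01851 and 0.04657; -0.06039 to 0.02779 without 1 array). Without 1 array, signs also turned for Foxo1 (-0.03787 to 0.1399), Jund (-0.1615 to 0.006117), Kcnk1 (-0.01591 to 0.1483), Msx2 (-0.1583 to 0.01669), Slc20a1 (-0.1922 to 0.02199) and Vdr (-0.0234 to 0.1804). None of these genes passed in any setting.

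List directions turned only where adjusted p was over 0.05. With the filter at the median these were adhesion (0.758), endothelial (0.921), skeletal muscle (0.921) and housekeeping (0.952) genes, and at the 25th percentile adhesion (0.648) and inflammation (0.643) genes. Fry turned inflammation (0.892), and passed 7 lists that camera did not: osteocyte (1.69e-05), vitamin D (0.000974), BMP and TGF-beta (0.00158), osteoclast regulation (0.00573), chondrocyte (0.00573), osteoblast matrix (0.036) and tenocyte (0.0395) genes. Without 1 array, adjusted p ran from 0.35 to 0.918 for adhesion, 0.386 to 0.822 for neural, 0.543 to 0.947 for transcription factor and 0.117 to 0.913 for skeletal muscle genes. Over their alternatives, adjusted p ran from 0.0758 to 0.921 for endothelial, 0.191 to 0.952 for housekeeping and 0.317 to 0.976 for inflammation genes. Of the called lists, hypoxia genes missed the threshold with the filters (0.0779 and 0.0572), smooth muscle genes with the filter at the median (0.0534), and DNA replication (0.185) and oxidative phosphorylation (0.0683) genes with fry. Signal over background limits low genes: 828 genes lay below the random control on all 6 arrays, and 2 of them passed.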

Other observations

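The gene groups and tests here were chosen after the values were seen, except the count over other splits of the arrays. Genes of retinoid metabolism and signalling rose in 8 of 27 measured members and fell in 2. The dehydrogenases Adh1 (3.48, SE 0.12), Adh7 (2.50, SE 0.18), Aldh1a1 (3.33, SE 0.11) and Aldh1a3 (1.95, SE 0.13), which oxidise retinol and retinal, rose with Cyp26b1 (2.16, SE 0.19), which breaks retinoic acid down. The receptor Rxra fell by 0.96. Secreted cartilage proteins rose in 8 of 17 members and fell in 0, or 1 with cyclic loess, including Cilp (3.74, SE 0.18), Otor (2.01, SE 0.13), Ucma (1.99, SE 0.17) and Matn4 (1.76, SE 0.14). Most members, with the risen Cnmd, Col11a1 and Comp, are also in the fixed chondrocyte list. Of those added to them, Cilp, Frzb, Ucma, Matn4 and Otor rose and Epyc did not pass. The count thus reflects how the list was chosen and is no separate result. The thyroid hormone activating deiodinase Dio2 (1.85, SE 0.14) rose, and the receptors Esr2 (-1.56, SE 0.16) and Thrb (-1.04, SE 0.19) fell.

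Guanylate-binding protein genes, which interferons induce, rose in 5 of 10 members and fell in 2, while the fixed interferon list had 7 lower of 27. Gbp6 (2.28, SE 0.14), Gbp4 (2.06, SE 0.13), Gbp10 (1.92, SE 0.22), Gbp8 (1.48, SE 0.15) and Gbp9 (1.17, SE 0.19) rose, and these neighbouring genes are similar in sequence, so probes can share signal. The 2 falls became 0 without differentiated replicate 2. Histone genes fell in 28 of 58 members and rose in 5, with a median of -0.49 and medians from -0.49 to -0.52 under the other scalings and from -0.40 to -0.60 without 1 array. Without differentiated replicate 2, 19 histone genes fell and 3 rose. Many are near-identical copies. Adjacent genes changed at least 2-fold in the same direction in 24 pairs, against a median of 7 and a highest value of 18 in 10000 random placements. The pairs include related genes such as Adh7 with Adh1 and Igfbp2 with Igfbp5. Of 1070 olfactory receptor genes, which bone cells are not known to use, 9 passed (0.841%, against 13.5% of all genes).

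Other splits of the 6 arrays into 3 and 3 gave at most 0 changed genes, against 2330 for the real groups, and at most 0 against 459 at 2-fold. Only 1 of the 10 splits, the real one, gave as many in each case, and 10 splits are too few for a share under 0.05. Every other split also mixes the real groups. The group difference then adds to the spread within each side and lowers the calls, so low counts there were to be foreseen. At an unadjusted p under 0.05 with limma the real groups gave 4577 genes and the highest other split, undifferentiated replicates 1 and 2 with differentiated replicate 1 against the rest, gave 2742. The arrays also divide that way on the second principal component, which holds 24.6% of the variance.

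Mitotic genes of differentiated replicate 3 lay 0.4877 above the mean of replicates 1 and 2 on the log2 scale. Random lists matched on intensity had a median gap of 0.0768 and an upper 95% limit of 0.151. Of these, 0 of 10000 reached the observed gap, so genes of like intensity shifted less on average. Random genes were drawn independently, while mitotic genes had an estimated correlation of 0.61, so such limits are too narrow. The gap was also tested after it was seen, so it cannot decide whether array contrast was the cause. DNA replication genes also lay higher on that array, by 0.2486 (upper limit 0.116, 0 of 10000). So did 4 of the 26 lists without cell cycle genes, with gaps of 0.269 for endoplasmic reticulum stress, 0.208 for oxidative phosphorylation, 0.185 for cholesterol synthesis and 0.129 for housekeeping genes. Neural (-0.161), smooth muscle (-0.102) and hypoxia (-0.037) genes lay below the lower limits of their random lists. More cycling cells in that culture is therefore a candidate explanation that cannot be told apart from a wider difference of this array or culture.

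Ndufa1 (-2.63) and Rnf113a1 (-2.20) are adjacent genes and fell together. Loss of a wider chromosome segment would lower their neighbours too, but the 3 measured genes on each side had a median of -0.295, with standard errors up to 0.139, far above the pair. Gm9 among them lay below the random control, where a loss could not show, and the median of the other 5 was -0.310. Akap14 and Rhox1 were also weak, at undifferentiated intensities of 420 and 612, under the array medians, so they test a loss less well. Upf3b (8845), Nkap (1050) and Rhox2a (1275) lay above the medians, with log2 changes of -0.31, -0.37 and -0.41. The annotated genes overlap by 17 bases, so shared signal could contribute, and it cannot be told apart from a joint fall because probe positions were not in the tables. A shared control of both genes during differentiation was not tested.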
